A study of Homo sapiens with 3 samples.

How the data were processed

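RNA from human bronchial smooth muscle cells, the contractile cells of the airway wall, was compared on 3 two-colour microarrays. Each array held RNA of cells infected with an empty adenoviral vector on one channel and RNA of mock-infected cells on the other. Per the labels, the type 5 vector carried no insert and was applied at a multiplicity of infection of 40 for 4 days. Both cell preparations received 3 cytokines (IL-1beta, TNF-alpha and interferon-gamma) at 10 ng/mL for 20 hours before harvest. All 3 arrays form 1 group, since the comparison lies within each array.

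The deposited values are 1 number per feature and array. They spread to both sides of a median below 0, and were read as log ratios of the 2 channels. The scanner, background correction, normalization, base of the logarithm and numerator dye are not given in the sources used here. Values are therefore printed as log-ratio units and no fold change is given. The deposited table holds 1081 features, and 1 value is missing, on the array with mock RNA in Cy3. Spot intensities and flags were not used here, so dim spots could not be told from bright ones. Of the features, 965 have 1 gene symbol in the platform annotation, 8 have several and 108 have none. Symbols were checked against the RefSeq gene table of GRCh38.p14 by gene number, and 964 matched with no symbol changed. No coordinates are given, because the sources name no genome build.

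Dye orientation came from the titles. One array has infected RNA in Cy3 (the infected-Cy3 array) and another has mock RNA in Cy3 (the mock-Cy3 array). The title of the remaining array names infected RNA but no dye number. A rule fixed before the data were examined set the sign. As deposited, the 2 arrays of opposite dyes correlated at r = -0.42 across 1080 features, below the limit of -0.3. By the rule, the values were taken to follow the dye, the mock-Cy3 array was turned (its sign changed), and the test used these 2 arrays only. The array without a dye number was then entered with either sign as an alternative. A feature lies on the positive side if its deposited value is positive where infected RNA carries Cy3. The positive side means higher in infected cells if the deposited ratio is Cy3 over Cy5, and lower in infected cells if it is Cy5 over Cy3. On either reading a dye effect of a single feature cancels in the turned mean. If the ratios were instead deposited as infected over mock, or the reverse, on both arrays, the turned mean would hold the dye effect. The sources used here do not exclude that. The plan had been to read positive values as infected over mock, from the titles. That reading needs values that run one way on all arrays, which the rule did not take them to do, so it was set aside and no direction is claimed.

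The test was limma 3.58.1 in R 4.3.3, an intercept fitted to the turned values of the 2 arrays with eBayes, followed by Benjamini-Hochberg adjustment at 0.05. The first fit used the deposited scale, as fixed before the data were examined. The array medians of -0.55 and 0.25 (after turning) then enter each feature's spread. A second fit, also set beforehand, subtracted each array's median first. Both fits shared 1 spread among all features, 0.64 units for a single value on the deposited scale and 0.40 with centred arrays. A feature whose 2 values disagree can therefore still pass. The labels do not say whether the arrays hold separate cultures or repeat hybridisations of the same extracts, so adjusted p-values measure only the spread between arrays, which may be technical. The median turned mean over all features was -0.17 units. Values of single features and genes are therefore given relative to each array's median, as mean ± SD with n = 2, and the number of arrays limits the precision.

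Of 25 gene lists fixed before the data were examined, 17 had at least 5 measured genes. They were tested with camera (preset correlation of 0.01), with fry and with an estimated correlation, on genes taken as the mean of their features, and a gene counts as called if any of its features was. Counts adjusted over the list alone are for centred arrays unless stated. The genes named in the text were fixed by rule. The first part takes 12 features per side with the largest deposited value on the weaker of the 2 arrays, features called on the deposited scale first, with the same sign on both. The rule was written for 3 arrays and was applied to the 2 in the fit. The second part takes the 2 genes with the largest mean in each list with fewer than 2 members called on the deposited scale, which was every tested list. The third part is a fixed set of 19 genes, most of inflammation, of which 8 were measured. Among those not measured were the adenovirus receptor CXADR, the contractile gene ACTA2, the proliferation gene PCNA and the reference genes GAPDH and ACTB. Genes named outside the rule are marked as chosen after their values were seen.

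The scripts were tested on simulated arrays of 1080 features with 50 changed features per size. On the deposited scale, 8% of changes of 1 unit, 58% of 1.5 units and 92% of 2 units were called, and 0% of unchanged features. With centred arrays, 12% of changes of 0.5 units, 84% of 1 unit and 100% of 1.5 units were called, and 0.568% of unchanged features. Noise was drawn independently for each array with 1 spread taken from the dye pair. Technical differences shared by both arrays were not simulated and could raise the share of unchanged features called. In simulated lists of 10 genes, camera called 10 of 10 lists shifted by 0.6 units and 0 of 10 unshifted lists. These genes were drawn independently with 1 spread and no array offset, whereas real genes may be correlated. The list means in the data ran from -0.29 to 0.32, and shifts of that size were not simulated.

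Alternatives covered centring, scaling, the sign of each array, arrays left out or averaged, missing values, the variance model, averaging per gene and a minimum change. A filter on dim spots was not run because intensities were not used here.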

Results

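Expression in infected and mock-infected bronchial smooth muscle cells was measured on 3 two-colour arrays of 1081 features, all after cytokine stimulation. The comparison asks which transcripts the empty adenoviral vector itself shifts in cytokine-treated cells. Deposited log ratios had medians of -0.30 on the array without a dye number, -0.55 on the infected-Cy3 array and -0.25 on the mock-Cy3 array. Their SDs across features were 0.44, 0.55 and 0.48. The largest value, 3.36, lay on the mock-Cy3 array, whereas the maxima of the other arrays were 1.22 and 1.28.

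On the deposited scale 3 features passed, all on the negative side, and 0 passed on the positive side (limma; 48 on both sides with an unadjusted p below the threshold). Whether the positive side is the infected or the mock side is not given in the sources used here. The 3 features belonged to IKBKE, a kinase of innate antiviral and NF-kappaB signalling, LRRC17, a leucine-rich repeat protein, and CDA, cytidine deaminase. Relative to the array medians, the means were -2.12 ± 2.11 for IKBKE, -2.10 ± 2.01 for LRRC17 and -2.10 ± 1.08 for CDA (SD, n = 2). Each had a limma adjusted p of 3.4e-04. For IKBKE and LRRC17 the SD was about as large as the mean. The infected-Cy3 array gave -0.62 for IKBKE, -0.68 for LRRC17 and -1.34 for CDA, while the turned mock-Cy3 array gave -3.61, -3.52 and -2.86. On the array without a dye number, CDA lay at 0.46, IKBKE at -0.13 and LRRC17 at -0.97. With the array without a dye number in place of either array of the pair, LRRC17 passed both ways, IKBKE did not pass without the mock-Cy3 array and CDA passed neither way. These fits were not centred, and without the mock-Cy3 array both medians (-0.55 and -0.30) favour the negative side. With all 3 arrays centred, LRRC17 did not pass (limma adjusted p = 0.11 with the deposited sign of the array without a dye number, 0.65 with it turned). Without the 5 features highest on the mock-Cy3 array, which include these 3, the deposited scale gave 0 calls.

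Across 1080 features, which are not independent replicates, the arrays of opposite dyes correlated negatively (Pearson r = -0.42, Spearman rho = -0.33). The array without a dye number correlated at r = 0.26 with the infected-Cy3 array and at r = -0.18 with the mock-Cy3 array. The mean of both arrays before turning, which holds any dye effect of a feature if both ratios have the same numerator dye, had a median of -0.36 and an SD across features of 0.28. The SD of the turned mean was 0.43, and the negative correlation fixes which of these SDs is larger.

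**Figure D1:**
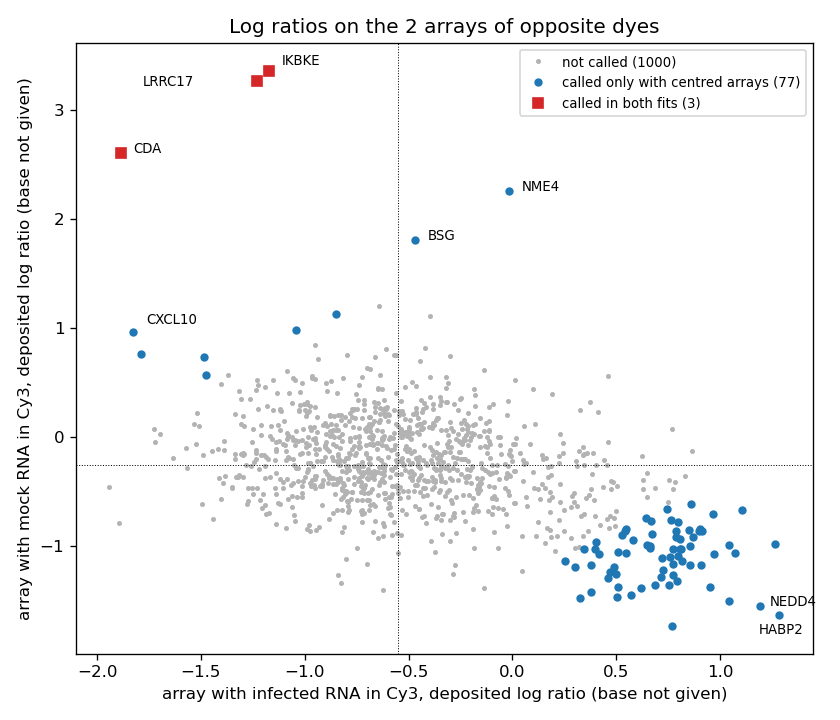
Deposited log ratio of each of 1080 features on the array with infected RNA in Cy3 (x axis) and on the array with mock RNA in Cy3 (y axis), with dotted lines at the array medians. The 3 features called in both fits lie at the upper left, and most of those called only with centred arrays form a group at the lower right, on the positive side.

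With each array centred on its median, 80 features passed, 69 on the positive side and 11 on the negative side, and IKBKE, LRRC17 and CDA were among them. Thus the positive share of calls was 0% on the deposited scale and 86.2% with centred arrays. The negative correlation of these same 2 arrays had set the sign of the mock-Cy3 array. Turning by that rule widens the turned means and narrows the spread between the arrays. The number of calls and their p-values therefore follow in part from the rule. Of the 80 calls, 78 had the same sign on both arrays, against 57.6% of all 1080 features. Selecting features by a large mean makes a shared sign likely by itself, so this count is no replication. The other 2 calls, NME4 and BSG, rested on the mock-Cy3 array alone and were named after their values were seen. When the array without a dye number was added to the centred fit, no feature passed (limma; smallest adjusted p = 0.082 with its deposited sign, and 159 features with an unadjusted p below the threshold). With its sign turned, 1 feature passed. In the order of feature numbers, 27 of the 69 positive-side calls fell in 1 stretch of 192 consecutive features, where the densest such stretch of shuffled orders held a median of 19 calls (highest 27). At widths of 48 and 96 features the densest stretches held 9 and 15 calls, against shuffle medians of 8 and 12. As many were reached in 2295 and 408 of 10000 shuffles. Values in the next paragraphs rest on the dye pair unless the array without a dye number is named.

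On the positive side, the 12 features named by rule passed with centred arrays and did not pass on the deposited scale. HABP2, a secreted hyaluronan-binding protease, was farthest from the median at 1.61 ± 0.32 (limma adjusted p = 4.8e-06 centred and 0.38 as deposited). NEDD4, a ubiquitin ligase, followed at 1.52 ± 0.31, and NME3, a nucleoside diphosphate kinase, at 1.42 ± 0.24. GARS1, the glycyl-tRNA synthetase, lay at 1.31 ± 0.27, PRPS1, which makes phosphoribosyl pyrophosphate, at 1.03 ± 0.61, and MAN2A1, a Golgi mannosidase, at 1.17 ± 0.60. CTSW, a cathepsin of cytotoxic lymphocytes, lay at 1.19 ± 0.38, MMP8, the neutrophil collagenase, at 1.04 ± 0.54, and SERPINI1, neuroserpin, at 1.22 ± 0.58. The interferon-inducible gene IFI6 lay at 1.17 ± 0.49, TMEM41B, an endoplasmic reticulum membrane protein, at 1.27 ± 0.77 and MFNG, a Notch-modifying glycosyltransferase, at 1.03 ± 0.60. The array without a dye number placed MFNG below its median, at -0.02, and the other 11 above it.

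On the negative side, 8 of the 12 features named by rule passed with centred arrays. Besides IKBKE, LRRC17 and CDA, CXCL10, a chemokine induced by interferon-gamma, lay at -1.24 ± 0.04 (limma adjusted p = 0.0013 centred and 0.49 as deposited). ELAVL4, a neuronal RNA-binding protein, lay at -1.13 ± 0.16 and KRT10, an epidermal keratin, at -0.96 ± 0.03. OSM, a cytokine of the IL-6 family, lay at -0.86 ± 0.52 and ITIH4, a plasma protein of the inter-alpha-trypsin inhibitor family, at -0.84 ± 0.76. The remaining 4 did not pass in either fit. Their means were -0.75 ± 0.49 for IL1B, -0.68 ± 0.41 for PTAFR, the receptor of platelet-activating factor, -0.63 ± 0.54 for CD180 and -0.55 ± 0.62 for ITGB5, an integrin subunit used in adenovirus entry. The array without a dye number placed CDA and IL1B above its median, at 0.46 and 0.08. It placed the others of the 12 below, with CXCL10 at -0.10. With that array in place of the infected-Cy3 array, the deposited-scale mean of CXCL10 was -0.68. In place of the mock-Cy3 array it gave -1.11, against -1.39 in the pair.

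None of the 17 gene lists passed camera (smallest adjusted p = 0.41, and 0.99 with an estimated correlation), and 0 passed fry (smallest adjusted p = 0.97). The estimated-correlation and fry tests rest on the spread between the arrays of the dye pair alone, so hardly any list could pass them. They do not count for or against a list effect. With the preset correlation, the smallest unadjusted camera p, below the threshold for 1 list, belonged to the oxidative stress and xenobiotic list. All 8 of its measured genes had means below the median, and 6 were below it on both arrays. Among them GSTM1, a glutathione transferase, was called with centred arrays at -0.87 ± 0.08, the 1 gene that also passed when adjusted over the list alone, while CYP1B1 at -0.40 ± 0.42 did not pass. On the array without a dye number, however, this list had a median of 0.26, above the array median.

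Among 16 measured cytokines and chemokines, 4 were called on the positive side with centred arrays and 0 on the negative side, and 5 passed when adjusted over the list alone, 4 on the positive side and IL1B on the negative side. CSF3, the granulocyte growth factor, lay at 1.204 ± 0.196 and IL10, an anti-inflammatory cytokine, at 1.08 ± 0.46. The list's median was 0.03, with 9 genes above and 7 below the array medians (camera adjusted p = 0.62). In the interferon-stimulated list, 8 genes were measured, and IFI6 and CXCL10 were called with centred arrays on opposite sides. Adjusted over the list alone, 2 of the 8 passed, and 1 passed on the deposited scale. The camera adjusted p of this list was 0.94, with the test pointing to the negative side and the median at 0.03.

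Of 19 proteases and inhibitors, 4 were called on the positive side with centred arrays and also passed when adjusted over the list alone. MMP3, stromelysin 1, lay at 1.06 ± 0.41, beside MMP8. The list's median was 0.19, with 8 genes above and 2 below the median on both arrays. Its camera adjusted p was 0.41 (0.99 with an estimated correlation, a test that hardly any list could pass here). Of 15 matrix genes, 2 were called with centred arrays, CCN1, a matricellular growth regulator, at 1.09 ± 0.36 and TGFBI, a TGF-beta-induced adhesion protein, at 1.05 ± 0.25. Adjusted over the list alone, 4 passed, 2 on each side. The 2 on the negative side, named after their values were seen, were COL6A3, a collagen VI chain, at -0.77 ± 0.97 and THBS1, thrombospondin 1, at -0.72 ± 0.06. COL4A2, chosen after its values were seen, was measured by 2 features on opposite sides, at 0.60 and -0.49. Among 26 growth factors and receptors, 3 genes were called on the positive side, and VEGFB at 1.002 ± 0.023 and TGFB2 at 0.97 ± 0.33 had the largest means, and 2 passed when adjusted over the list alone. The 2 lists had camera adjusted p-values of 0.92 and 0.94. The growth factor list had a median of -0.07 and a mean of 0.05, so these differed in sign.

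In the cytokine receptor and JAK-STAT list, 1 of 15 genes was called with centred arrays. This was IL1RN, the IL-1 receptor antagonist, at 0.84 ± 0.50, while IFNAR1, a chain of the type I interferon receptor, lay at 0.74 ± 0.44 without passing. Of 6 heat shock genes, HSPA1A was called at 0.91 ± 0.31, and HSP90AA1 at 0.43 ± 0.38 did not pass. In each of these lists 1 gene passed when adjusted over the list alone, and the camera adjusted p of both was 0.75. Of 9 genes of the NF-kappaB list, 0 were called in either fit, with NFKB2 at 0.61 ± 0.31 and TNFAIP6 at 0.46 ± 0.35. Its median was -0.05 and its mean 0.08 (camera adjusted p = 0.92).

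Genes of growth, damage and entry also gave no calls in either fit, nor when adjusted over each list alone. Of 19 proliferation genes, TYMS, thymidylate synthase, lay at 0.82 ± 0.68 and CDC6, a replication licensing factor, at -0.59 ± 0.61. Of 12 genes of the p53 and DNA damage list, 10 had means below the median. In this list ERCC1 lay at -0.33 ± 0.15, while FAS was measured by features at 0.64 ± 0.19 and 0.09 ± 0.14. Of 12 apoptosis genes, BIK lay at 0.67 ± 0.31 and BCL2L1 at -0.39 ± 0.08. Of 13 immediate-early and MAP kinase genes, MAP2K6 lay at -0.71 ± 0.61 and MAPK9 at -0.51 ± 0.10. Of 6 genes of adenovirus entry, ITGB1 lay at -0.64 ± 0.20 and ITGB5 at -0.55 ± 0.62. Of 8 airway receptor and eicosanoid genes, ADORA1 lay at 0.54 ± 0.86 and PTGER4 at 0.45 ± 0.15. The smallest camera adjusted p of these lists was 0.62.

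Markers of other cell types were compared in the same way. Of 8 epithelial markers, 6 had means above the median, KRT18 was called with centred arrays at 1.04 ± 0.17, and DSP at 0.80 ± 0.31 did not pass over all features. Adjusted over the list alone both passed, and the camera adjusted p was 0.41. Of 5 endothelial markers, 0 were called, with SELE at 0.46 ± 0.23 and KDR at -0.30 ± 0.14 (camera adjusted p = 0.92; median 0.02, mean -0.007). The leukocyte markers measured were CD4, CSF1R, ITGAM and PTPRC, too few for a test, with means from -0.29 to 0.22. The contractile and ribosomal protein lists had 0 members among the measured genes. The antigen presentation list had 4, complement 3, glycolysis 2, innate sensing 1 and fibroblast markers 1, also below the minimum of 5. The 4 antigen presentation genes, not covered by the naming rule, were uncalled, with HLA-DRA at -0.62, PSME1 at -0.69, TAPBP at -0.12 and PSMB9 at 0.06.

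**Figure D2:**
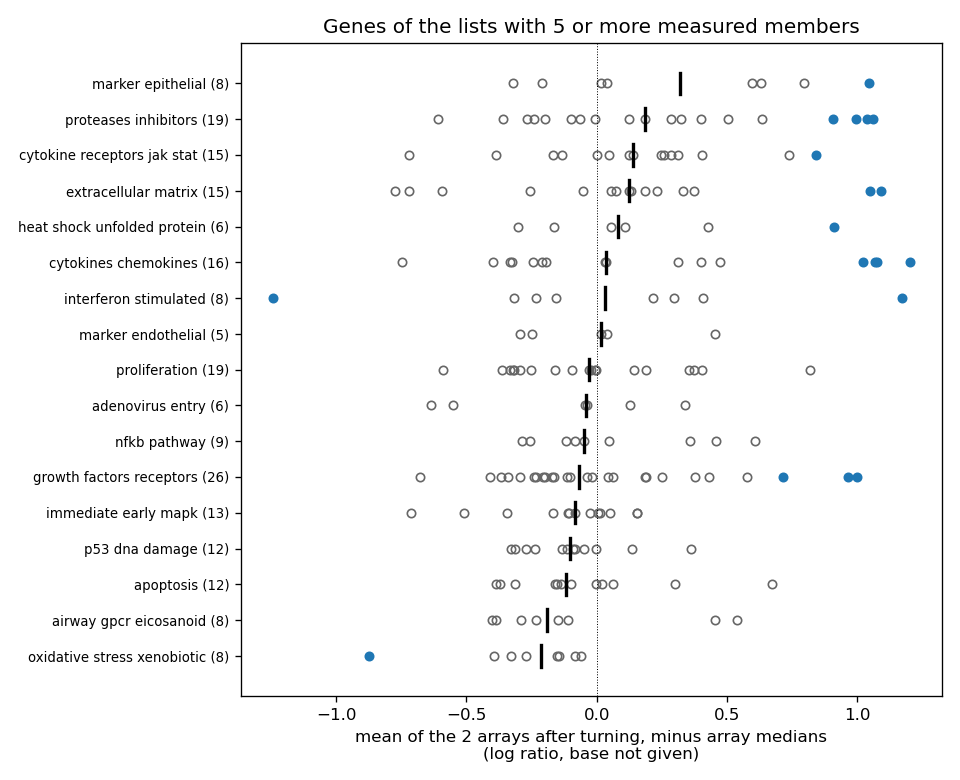
Mean of the turned dye pair relative to the array medians for each measured gene of the 17 tested lists, with list sizes in parentheses. Filled circles are genes called with centred arrays, open circles are genes not called, and black bars are list medians, which range from -0.21 to 0.32.

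Of the 8 measured genes of the fixed set, all of inflammation or growth arrest, 0 were called in either fit. IL6 lay at -0.20 ± 0.51, CXCL8 at 0.31 ± 0.31 and CCL5, a T-cell chemokine, at 0.03 ± 0.69. The adhesion molecule VCAM1 lay at -0.08 ± 0.09, the inducible nitric oxide synthase NOS2 at -0.06 ± 0.03 and the cell cycle inhibitor CDKN1A at -0.09 ± 0.41. The transcription factors IRF1 and NFKB1 lay at 0.30 ± 0.13 and 0.05 ± 0.36. With centred arrays, the simulation called 12% of changes of 0.5 units, so differences of that size were mostly not detectable with 2 arrays.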

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

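The count of calls depended on centring, on the arrays used and on the variance model. The deposited scale gave 3 calls, and choices set before the data were examined gave 80 with centred arrays, 84 when these were also scaled to one spread and 22 with a trended, robust variance. Those 22 all lay on the positive side and included none of the 3. No intensities entered that fit, so its variance was trended on the tested mean itself, which can by itself move calls to 1 side. The count was 6 when the dye pair was averaged and set beside the array without a dye number, 1 when that array joined with its sign turned, and 0 with the mock-Cy3 array unturned (limma; 37 unadjusted). Leaving out each array of the dye pair, with the array without a dye number in its place, gave from 3 to 78 calls. On the deposited scale, not relative to the medians, CDA fell short of the threshold both ways (-1.22 with limma adjusted p = 0.45 without the infected-Cy3 array, -0.86 with 0.071 without the mock-Cy3 array), and IKBKE did so without the mock-Cy3 array (-0.80, limma adjusted p = 0.092), against -2.25 and -2.26 in the pair. The 78, without the mock-Cy3 array, all lay on the negative side, where the medians of both remaining arrays lie. The 3 calls without the infected-Cy3 array shared 2 with the deposited-scale fit. The same 3 were called under 4 other settings, the missing-value rule, averaging per gene, a minimum change (a fold of 1.2, were the logarithm base 2) and adding the array without a dye number with its deposited sign. The first 3 of these settings leave the values of these features as they were, so the shared calls there say little. Alternatives chosen after seeing the data gave, with centring, 0 calls with the array without a dye number as deposited, 1 with it turned, 0 with the mock-Cy3 array unturned (limma; 3 unadjusted), and 83 without the 5 features highest on the mock-Cy3 array. Without these 5 and without centring, 0 passed. With the mock-Cy3 array unturned, the deposited-scale means changed sign to 1.09 for IKBKE, 1.02 for LRRC17 and 0.36 for CDA, or to 1.49, 1.42 and 0.76 with centring, none called. The negative correlation that set the sign also widens the spread between the unturned arrays, so few calls were likely there. Of the gene lists, 0 passed on the deposited scale. Leaving out arrays gave from 0 to 2, the averaged pair 1, all 3 arrays with deposited signs 1, and the unturned mock-Cy3 array 3. The protease list passed in these settings, except without the infected-Cy3 array (camera adjusted p = 0.16). Its adjusted p ran from 4.0e-04 to 0.99 over 10 alternatives, the highest with an estimated correlation. The cytokine list passed without the mock-Cy3 array (0.020) and with it unturned (0.0069), and the proliferation list with it unturned (0.031). Each list call failed with an estimated correlation, run there after seeing the data (adjusted p 0.91 to 0.95). So few arrays let hardly any list pass it. The cause was not tested. The filter on dim spots was not run.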

Other observations

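The calls with centred arrays were set before the data were examined, while the tests of position, markers, the array without a dye number and spot faults were chosen after results were seen. Among the 80 features called with centred arrays, several positive-side genes fell outside the naming rule and were picked after their values were seen. IFNG lay at 1.12 ± 0.30, IL1A at 1.07 ± 0.41, IL15 at 1.02 ± 0.61 and IL16 at 1.17 ± 0.10 (SD, n = 2). Interferon-gamma was added to both cell preparations, and the IFNG value concerns the transcript, not the added cytokine. Proteases included MMP13 at 0.91 ± 0.57 and ADAM9 at 0.998 ± 0.568. Hedgehog receptor PTCH1 lay at 1.15 ± 0.03 and WFDC2, a secreted epithelial protein, at 1.40 ± 0.11. HGF, a growth factor made by mesenchymal cells, was measured by 3 features at 0.98, 0.85 and 0.32, of which the 2 higher passed. Their spot intensities were not used here.

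The first pattern is the group of 69 positive-side calls with centred arrays, to which position may contribute, since 27 of the 69 fell in 1 stretch of 192 consecutive feature numbers (densest stretch of shuffled orders, median 19 and highest 27; permutation p over widths of 48, 96 and 192 features = 0.0012). Over all features, the best of a set of groupings of the feature numbers, nearly all periodic, was also compared with shuffles. It explained 0.0113 of the variance of the turned mean beyond the share expected from its group count. As much was reached in 885 of 1000 shuffles. Periodic groups can hardly see 1 stretch, so this result does not count for or against it. The numbering follows gene family at least in part, since cytokine genes such as IL1B, CCL5, IFNG and OSM have close numbers. Whether it also follows the slide layout is not given in the sources used here. A dye effect of single features cancels in the turned mean if both ratios have the same numerator dye, and stays open otherwise, as do scarce transcripts, since the median of 17 leukocyte, epithelial and endothelial markers minus that of 15 matrix genes was -0.107 units (permutation test, two-sided p = 0.37). A difference between the infected and mock RNA that other hybridisations also carry may contribute too. The array without a dye number correlated with the turned mean at r = 0.26 across features (largest of 10000 shuffles 0.12). Features are not independent, so the shuffles are a rough guide only. Were the ratios deposited as infected over mock, a dye effect could give the same correlation, which cannot tell these causes apart. On the array without a dye number, 57 of the 69 features lay above the median, though by a mean of 0.28 units against 1.05 on the pair. Whether infection made that difference was not tested.

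The second pattern is the 5 highest values of the mock-Cy3 array, IKBKE, LRRC17, CDA, NME4 and BSG, from 1.80 to 3.36 as deposited. If spot faults on that array alone were the whole cause, these features would fall anywhere on the infected-Cy3 array, yet 3 of the 5 fell in its lowest 10% (IKBKE, LRRC17 and CDA; exact binomial one-sided p = 0.0086). Their percentiles were 7.87, 5.93 and 0.278, so the count depends on the cut. The test was chosen after these 3 had been called, and it treats the 5 features as independent. Its p-value is therefore a description only. The size of the 5 values was not shared by the infected-Cy3 array, where NME4 and BSG lay at the 82.2 and 55.8 percentiles. Of the 5, 3 (IKBKE, LRRC17 and BSG) lay in the stretch of 192 feature numbers named above. The mean of both arrays before turning, relative to its median, was 1.48 for NME4, 1.45 for IKBKE, 1.38 for LRRC17 and 1.02 for BSG. These were the largest of all features, and CDA was lower. A high value on 1 array raises this mean by itself, so it cannot tell a dye effect from a spot fault. Spot faults may still contribute to the size of all 5. No biological explanation was tested for this pattern.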
